A study of Mus musculus with 6 samples.

How the data were processed

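CTBP2, a transcriptional co-repressor, was profiled by chromatin immunoprecipitation and sequencing in mouse bone marrow-derived macrophages, which are macrophages grown from marrow cells in culture. Per the labels, 3 libraries came from cells given vehicle (PBS) and 3 from cells given 100 ng/ml lipopolysaccharide (LPS), a bacterial cell wall component, for 3 h. The labels number the replicates but do not say that they came from separate animals or cultures. The limma p-values of sites therefore measure only the spread between these libraries, which may be technical. Those of the permutation and Fisher's exact tests compare genes or sites and do not measure that spread. No input or control immunoprecipitation was analysed here.

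All values came from 1 deposited table of 62236 sites, of which 61976 were 1001 bp wide. The 6 deposited signal columns hold a normalised value per site and library. In each column the low values (up to 300 reads) were whole multiples of 1 step within 0.1 read, as read counts multiplied by 1 factor per library would be, and the authors' values are read here in that way. What set that factor is not given in the sources used here. The deposited log2 concentrations equalled the log2 mean of those values within 0.000377. The deposited log2 fold was smaller than the difference of the group concentrations, with a median ratio of 0.769 at sites with a deposited FDR under 0.05. The deposited p-values gave the deposited FDR by the Benjamini-Hochberg procedure within 4.33e-06. Per the submitters' processing notes, the tools were FastQC, BWA 0.7.17, Picard 3.2.0, SAMtools 1.9, deepTools 3.5.1, bedtools, MACS3 3.0.0a5, R 4.4.1 and DiffBind 3.16. The same notes list the builds mm39, GRCm39 and mm10 without saying which step used which. Whether peaks were called per library or on pooled reads is not given in the sources used here.

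Depth was estimated from the step of each column, taken as 1 read. On this reading the libraries held between 3243258 and 4553177 reads in the sites, with a median of 39 to 55 reads per site. A count model was not used, because the table holds normalised values. The test was limma 3.58.1 in R 4.3.3 (trend and robust options) on log2(value + 1), with all 6 libraries, no covariates and Benjamini-Hochberg adjustment over all sites. Folds are on the log2(value + 1) scale, which understates changes at low sites. The design, the gene lists, the rule for named sites and most alternatives were fixed before the data were examined.

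The table pairs sites with genes, and its positions were checked. Of its 8393 genes, 8054 matched a GRCm38.p6 gene table by symbol, and 83.5% of those had a start or end within 100 bp of it. The sites did not line up with these gene starts. An offset was therefore measured within the table itself, after the mismatch was seen. For each gene, shifts up to 1 Mb in steps of 250 bp were scored by whether a site centre lay within 500 bp of the shifted start, and a dynamic programming path along each chromosome (penalty 12, assumed share of starts with a site 0.35, at least 5 hits per stretch) picked the shift. It placed 8377 genes in 116 stretches, with a median absolute shift of 123 kb. With the path fitted on every other gene, 70.1% of 8388 held-out gene starts had a site within 500 bp. The share was 9.61% with no offset and 7.96% with the offset reversed. Site and gene positions are therefore on different coordinates in most of the genome. No chain file was used and no shifted coordinate is given. Site coordinates are printed as the table gives them, and their build is not stated in it. Each named site carries the gene the table names and, where it differs, the gene with the nearest placed start, called the gene at the measured offset. Only genes in the table could be named, so a nearer gene outside it would be missed.

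The named sites were, by rule, the 10 higher and the 10 lower sites with the smallest adjusted p (1 per gene), up to 4 genes per list with the smallest adjusted p, and 15 genes fixed in advance. The rule was applied to the names in the table and again to the genes at the measured offset. Not every gene the rule takes is reported here. The 13 gene lists covered inflammatory mediators, the NF-kB pathway, interferon response, immediate early and AP-1 genes, anti-inflammatory feedback, macrophage identity, lipid metabolism, the CTBP co-repressor complex, glycolysis, neutrophil, lymphocyte, erythroid or stromal, and housekeeping genes. For each list, the number of genes with a called site was compared with 10000 random lists matched on sites per gene and mean concentration, with a two-sided permutation p adjusted over 26 tests. The smallest unadjusted p these could give is 0.0002. Random lists did not keep neighbouring genes together, so the permutation p treats list genes of a shared region as independent and may be too small. Lists were also tested with limma's camera and fry. Promoter shares were compared by Fisher's exact test, in which sites are not independent replicates.

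Each path was tested on simulated data. In simulated libraries for LPS against vehicle, with 200 of 62236 sites changed, limma on the deposited scaling recovered 0% of 100 sites changed 2-fold and 55% of 100 changed 4-fold, with 0 false calls. On median-centred values it recovered 75% and 100%, with 4 false calls. After median-centring, the simulated within-group SD was 0.266 on the log2 scale, and the real one was 0.266. This match is largely built in, because the simulated spread was estimated from the same centred residuals. It leaves out the differences in library level that the deposited scaling holds, which the simulation took from the real library medians. The offset path recovered the shift within 1 kb for 99.6% of 1056 simulated genes. These genes shared a few simulated shifts, all smaller than the largest real ones, so the path was checked only in part. The list test gave p under 0.05 in 2.5% of 200 random lists and in 20 of 20 planted lists. There sites were called at random and independently, so this does not cover called sites that cluster in genes or regions. Python 3.11.15 with numpy, pandas and scipy did the remaining steps. Alternatives included other thresholds, pseudocounts of 0.5 and 10, median-centred and quantile normalised values, a filter on mean values under 20, autosomes only, the replicate number as a block, and leaving out each library. Motif and GC content tests were planned and not run, since no genome sequence was used here.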

Results

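CTBP2 signal was measured at 62236 sites in 3 vehicle and 3 LPS libraries of mouse bone marrow-derived macrophages. If the smallest step of each column is 1 read, depth was similar across libraries, at 3243258 to 4553177 reads in sites. The deposited values were less even. Their median per site was 35.5, 37.3 and 73.0 in vehicle replicates 1, 2 and 3, and 37.1, 48.8 and 61.0 in LPS replicates 1, 2 and 3. Site values correlated at 0.890 to 0.932 between libraries of a group and at 0.690 to 0.763 between groups, across sites that are not independent. The first principal component of the deposited log2 values (61.8% of variance) followed the level of the library, and the second (28.6%) separated LPS from vehicle. After median-centring, the first component (63.9%) separated the groups.

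The comparison of LPS with vehicle asks where CTBP2 binding changes when macrophages meet an inflammatory stimulus. Of the 10 higher sites with the smallest adjusted p (1 per gene), 7 lay nearest to genes of the inflammatory mediator list at the measured offset. These were the chemokine genes Ccl5, Cxcl2, Cxcl10, Cxcl1 and Ccl4, the cytokine gene Tnf, and Acod1, which encodes the enzyme that makes itaconate. At these 7 sites the signal rose between 3.27 and 5.16 on the log2 scale (n = 3 libraries per group). This naming was chosen after the data were seen. The table names other genes for these 7 sites, and of the 10 chosen in the same way under its names 1, that of Ccl9, was of a gene in the list. Of sites with higher CTBP2 signal in LPS there were 1178, and of sites with lower CTBP2 signal in LPS 30, at a limma adjusted p under 0.05, so 97.5% of called sites were higher. On median-centred values 9990 were higher and 8354 lower, and the share of higher sites was 54.5%. The number of higher sites was 272, 210 and 10062 without vehicle replicates 1, 2 and 3, and 148 and 175 without LPS replicates 2 and 3, while that of lower sites was 6, 1 and 227 without vehicle replicates 1, 2 and 3, and 2, 0 and 2 without LPS replicates 1, 2 and 3 (310 lower at an unadjusted p under 0.05 where limma called 0).

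The strongest gain was at chromosome 11, 83417329 to 83418329, inside Ccl5 at the measured offset and named Taf15 in the table. Its value was 22.2 ± 8.39 (SD, n = 3) in vehicle and 943 ± 646 (SD, n = 3) in LPS. The log2 fold was 5.16 (SE 0.45, limma adjusted p = 3.82e-25). At chromosome 5, 91053474 to 91054474, 2.24 kb past the placed start of Cxcl2 and named Mthfd2l in the table, the value went from 27.5 ± 16.7 to 901 ± 470 (SD, n = 3 each). That log2 fold was 5.01 (SE 0.45, limma adjusted p = 2.21e-24). The Acod1 site (chromosome 14, 103291074 to 103292074, named Mycbp2) rose from 15.9 ± 8.96 to 566 ± 371, a log2 fold of 4.98. The Cxcl10 site (chromosome 5, 92493856 to 92494856, named Scarb2) rose from 14.7 ± 6.83 to 358 ± 186, a log2 fold of 4.42. The Tnf site (chromosome 17, 35418184 to 35419184, named H2-Q6) rose from 84.8 ± 74.2 to 927 ± 299, a log2 fold of 3.72. The Cxcl1 site (chromosome 5, 91041189 to 91042189, named Mthfd2l) rose by a log2 fold of 3.71, and the Ccl4 site (chromosome 11, 83555262 to 83556262, named Ccl9) by 3.27. Sites nearest to Adora2a (named Bcr), Cd40 (named Zfp335) and Kcnk6 (44.4 kb away, named Eif3k) rose by log2 folds of 3.60, 3.29 and 3.29, and one of St3gal3, the same gene under both namings, by 3.18. These 11 sites passed the test on the deposited, median-centred and quantile normalised values and without each single library.

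**Figure D1:**
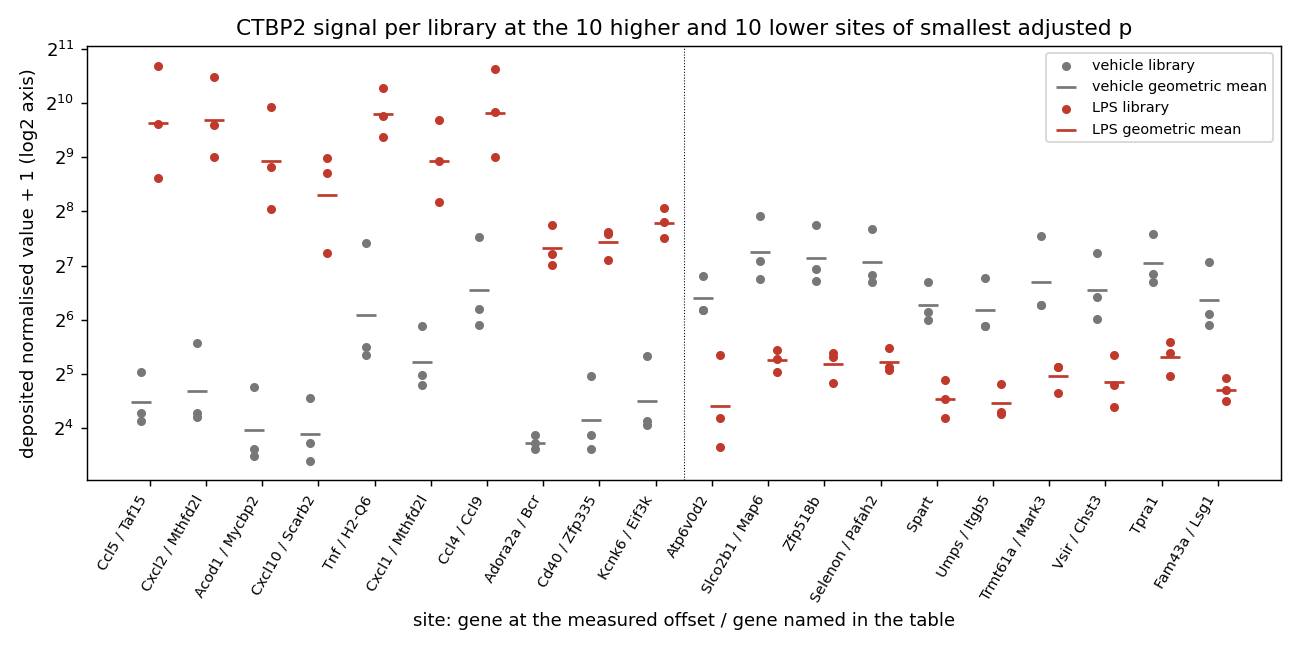
Deposited normalised value plus 1 (log2 axis) in each of the 6 libraries at the 10 higher and 10 lower sites with the smallest adjusted p, by gene at the measured offset and, where it differs, gene named in the table; points are libraries and dashes geometric means of 3. At the Ccl5 site the vehicle mean was 22.2 and the LPS mean 943, and at the Atp6v0d2 site the vehicle mean was 84.8 and the LPS mean 22.9.

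The lower sites changed less, with a median log2 fold of -1.66. The smallest adjusted p was at a site of Atp6v0d2, which encodes a subunit of the vacuolar proton pump, under both namings. This site at chromosome 4, 19855885 to 19856885, lay 66.2 kb from the placed gene start and had 84.8 ± 22.3 in vehicle and 22.9 ± 15.0 in LPS (SD, n = 3 each), with a log2 fold of -2.00 (SE 0.45, limma adjusted p = 0.00202). Its log2 fold was -2.10 without vehicle replicate 2 and -1.62 without LPS replicate 2, and neither passed the test. A site nearest to Slco2b1 (named Map6) at chromosome 7, 99323687 to 99324687, had 161 ± 71.3 and 37.4 ± 5.36, a log2 fold of -2.00. Sites nearest to Zfp518b, Selenon (named Pafah2), Spart, Umps (named Itgb5), Trmt61a (named Mark3), Vsir (named Chst3), Tpra1 and Fam43a (named Lsg1) had log2 folds from -1.95 to -1.65. Those of Zfp518b and Spart lay 946 and 515 kb from the placed start, and the median distance of lower sites was 112 kb. The Slco2b1 site and these 8 lost their call without vehicle replicate 2 and without LPS replicates 1, 2 and 3, each taken out alone, as did those of Spart, Umps, Trmt61a, Tpra1 and Fam43a without vehicle replicate 1. Where the call was lost, the log2 fold was -2.10 to -1.89 at the Slco2b1 site and -2.06 to -1.48 at the 8.

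The median vehicle value of the higher sites was 23.1, at the 8.2nd percentile of all sites, and their median LPS value was 87.8. The lower sites had 110, at the 87.2nd percentile, and 31.5. Sites are called on these same values, so part of this is built in, and the median-centred higher sites had a median vehicle value of 31.1, at the 20.6th percentile. Of the 1178, 378 rose over 4-fold, and in 1160 all LPS libraries lay above all vehicle libraries. Over all sites the LPS libraries lay wholly above the vehicle libraries at 9.01% and wholly below at 5.36%. Chance gives 5% each only for libraries of like level. The library medians differed, with the highest in a vehicle library, and all sites share these levels. The 5% is therefore not the share that unchanged sites would give here, and no conclusion is drawn from the comparison. Under the authors' own calls in their deposited table, 2497 sites were higher and 230 lower at an FDR under 0.05, and 1168 and 29 of these were also called here.

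**Figure D2:**
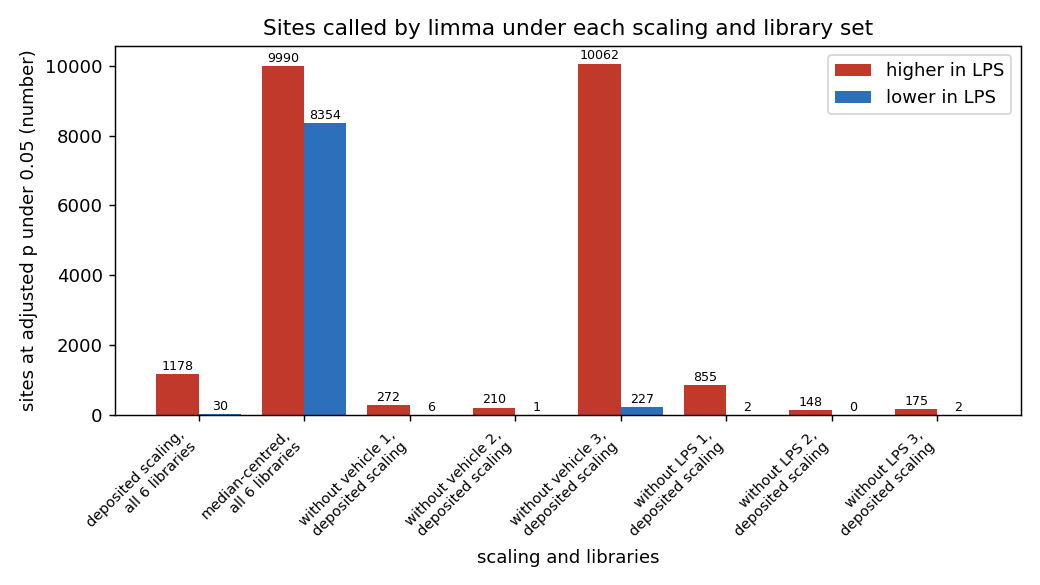
Number of sites (vertical axis) called higher (red) or lower (blue) in LPS by limma at an adjusted p under 0.05, for the deposited scaling, the median-centred values and the deposited scaling without each library. The deposited scaling gave 1178 higher and 30 lower sites and the median-centred values 9990 and 8354.

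Inflammatory mediator genes had a higher site more often than matched genes, though random lists did not keep neighbouring genes, such as Cxcl1 and Cxcl2, together. Under the names in the table, 17 of 40 measured genes did, against a mean of 5.61 in matched random lists (permutation adjusted p = 0.0026). In camera the list had an adjusted p = 0.999 with an estimated correlation under the table's names and 0.962 at the offset. The call under the table's names ended on median-centred values, with 25 genes against 20.0 (permutation adjusted p = 0.473), and within 10 kb of the named start, with 3 against 1.20 (permutation adjusted p = 1). At the measured offset 34 of 40 did, against 7.01 (permutation adjusted p = 0.00173), and on median-centred values 40 of 40, against 24.1 (permutation adjusted p = 0.00173). Besides the chemokine genes above, Il1b (log2 fold 2.76, 8.17 kb from the placed start, named Slc20a1), Il6 (2.64, 133 kb upstream, named Tyms) and Il12b (2.34, the same gene under both namings) had sites that rose at the offset and kept the call without each library. A site at the placed start of Nos2 (named Lyrm9), which encodes inducible nitric oxide synthase, rose by 1.85 and lost its call without vehicle replicate 1 or 2 and without LPS replicate 2 or 3, where the log2 fold was 1.56 to 1.80. Of the 462 sites of this list at the offset, 64 were higher over all sites and 104 when adjusted over the list alone, and under the table's names 33 and 50 of 373. Without vehicle replicates 1, 2 and 3 and LPS replicates 1, 2 and 3 the genes with a higher site at the offset numbered 23, 18, 40, 31, 19 and 17, and under the table's names 6, 5, 27, 15, 4 and 4.

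Genes of the NF-kB pathway also passed under both namings on the deposited values. Under the table's names 11 of 27 had a higher site, against 3.42 in matched lists (permutation adjusted p = 0.0026), and at the offset 19 of 25, against 4.56 (permutation adjusted p = 0.00173). In camera, adjusted p = 0.999 with an estimated correlation under the table's names and 0.962 at the offset. On median-centred values the call under the table's names ended, with 21 genes against 14.1 (permutation adjusted p = 0.0546), as it did within 10 kb of the named start, with 4 against 0.883 (permutation adjusted p = 0.426). At the offset it held on median-centred values, with 24 genes against 16.7 (permutation adjusted p = 0.0052), and did not in camera with an estimated correlation (adjusted p = 0.0767). Tnfaip3, an inhibitor of NF-kB signalling, had 9 of 29 sites higher under the table's names and 10 of 45 at the offset, on the deposited values. Its site at chromosome 10, 18901997 to 18902997, rose by a log2 fold of 2.46 (SE 0.45, limma adjusted p = 3.96e-05). Sites of the deubiquitinase gene Cyld (2.72, both namings), Cd40 (3.29) and the kinase gene Ikbkb (2.58, named Gpat4) rose too, and all of these 4 genes kept the call without each library. The sites of Cyld, Cd40 and Ikbkb lay 46.6, 5.90 and 1.65 kb from the placed starts. Nfkbia, which encodes the inhibitor IkB-alpha, had 5 of 20 sites higher under the table's names and 3 of 19 at the offset. Of these, the site with the smallest adjusted p under the table's names (log2 fold 2.39, nearest to Psma6 at the offset) lost its call without vehicle replicate 2 (2.03). The one at the offset (1.67, both namings) lost it without vehicle replicate 1 or 2 and without LPS replicate 2 or 3, where the log2 fold was 1.25 to 1.70. Of the list's sites, 28 of 284 under the table's names and 43 of 318 at the offset were higher, and 47 and 76 when adjusted over the list alone. Without vehicle replicates 1, 2 and 3 and LPS replicates 1, 2 and 3 the genes with a higher site at the offset numbered 10, 7, 25, 18, 7 and 7, and under the table's names 6, 3, 20, 9, 4 and 4.

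Interferon response genes passed at the offset and, under the table's names, in some settings. Under the table's names 10 of 38 had a higher site, against 4.34 in matched lists (permutation adjusted p = 0.0884), and at the offset 17 of 38, against 5.67 (permutation adjusted p = 0.00173). In camera its adjusted p = 0.999 with an estimated correlation under the table's names and 0.962 at the offset. Under the table's names the list did not pass on median-centred values, with 22 genes against 17.8 (permutation adjusted p = 0.725), within 10 kb of the named start, with 2 against 1.01 (permutation adjusted p = 1), within 1 kb of it, or without any single library but LPS replicate 1 (permutation adjusted p from 0.702 to 1). It passed there at an FDR of 0.01 (permutation adjusted p = 0.0485), with lists matched on sites per gene alone (permutation adjusted p = 0.0468) and without LPS replicate 1 (permutation adjusted p = 0.0139). Sites nearest to the antiviral genes Mx2 (log2 fold 2.59, named Mx1) and Rsad2 (2.40, named Cmpk2) rose, as did those of Gbp7 (2.37, named Pdlim5) and Parp14 (2.25, named Slc49a4). All of these 4 calls were lost without LPS replicate 3, where the folds (not log2) were 4.18, 3.73, 4.03 and 4.07, against 6.04, 5.27, 5.17 and 4.76 with all libraries. That of Mx2 was also lost without vehicle replicate 1 (3.71-fold) and that of Parp14 without LPS replicate 2 (4.52-fold). The Mx2 site was not among the authors' own calls (deposited log2 fold 0.841, deposited FDR 0.0538). Of the list's sites, 14 of 292 under the table's names and 24 of 373 at the offset were higher, and 17 and 50 when adjusted over the list alone. At the offset the list's adjusted p was 0.0745, 0.137, 1 and 1 without vehicle replicate 1, vehicle replicate 2, LPS replicate 2 and LPS replicate 3, where 6, 5, 3 and 0 genes had a higher site by limma.

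The inflammatory mediator and NF-kB lists passed at the offset without each single library. Under the table's names the inflammatory list did not pass without vehicle replicate 1, 2 or 3 or LPS replicate 2 or 3 (adjusted p = 0.101, 0.499, 0.307, 0.372 and 0.621). The NF-kB list did not without vehicle replicate 2 or 3 or LPS replicate 2 or 3 (0.894, 0.307, 0.125 and 0.156). With camera's preset correlation these lists, interferon response and anti-inflammatory feedback were called higher in both namings. With the replicate block, anti-inflammatory feedback did not pass under the table's names (camera adjusted p = 0.0502). None of these lists held with an estimated correlation, where all 13 lists had a camera adjusted p = 0.999 under the table's names and 0.962 at the offset. On the deposited values that correlation was 0.765 to 0.895 and 0.771 to 0.897 across the lists, housekeeping genes included. Median-centring brought it to at most 0.103 and 0.22. With a correlation so high in every list, the test on the deposited values could not tell these lists from the others. On median-centred values, inflammatory mediators, NF-kB, interferon response and anti-inflammatory feedback had an adjusted p of 0.0705, 0.0705, 0.262 and 0.0705 with an estimated correlation under the table's names, and of 0.0476, 0.0767, 0.189 and 0.0476 at the offset. With limma's fry, which asks whether the sites of a list move 1 way on balance and does not compare lists, the inflammatory list had an adjusted p of 0.906 under the table's names and 0.953 at the offset on the deposited values, and of 0.00113 and 0.000884 on median-centred values. By fry on median-centred values 8 of the 13 lists moved up in each naming, and 1 moved down at the offset, erythroid or stromal genes (adjusted p = 0.0138). Those that moved up in both were inflammatory mediators, NF-kB, interferon response, anti-inflammatory feedback, the CTBP co-repressor complex, glycolysis and neutrophil markers. The neutrophil marker list moved up (adjusted p = 0.00113 under the table's names and 0.00132 at the offset). Lymphocyte markers moved up under the table's names (adjusted p = 0.0128) and did not pass at the offset (adjusted p = 0.595), and immediate early genes moved up at the offset (adjusted p = 0.012) and did not pass under the table's names (adjusted p = 0.656). The preset camera direction was down, without passing, where the mean log2 fold was above 0 for immediate early genes under the table's names, for macrophage identity and lipid metabolism genes in both namings, for erythroid or stromal genes under the table's names and for housekeeping genes at the offset. The median of the lipid metabolism list in both namings, and of the erythroid or stromal list under the table's names, was below 0.

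**Figure D3:**
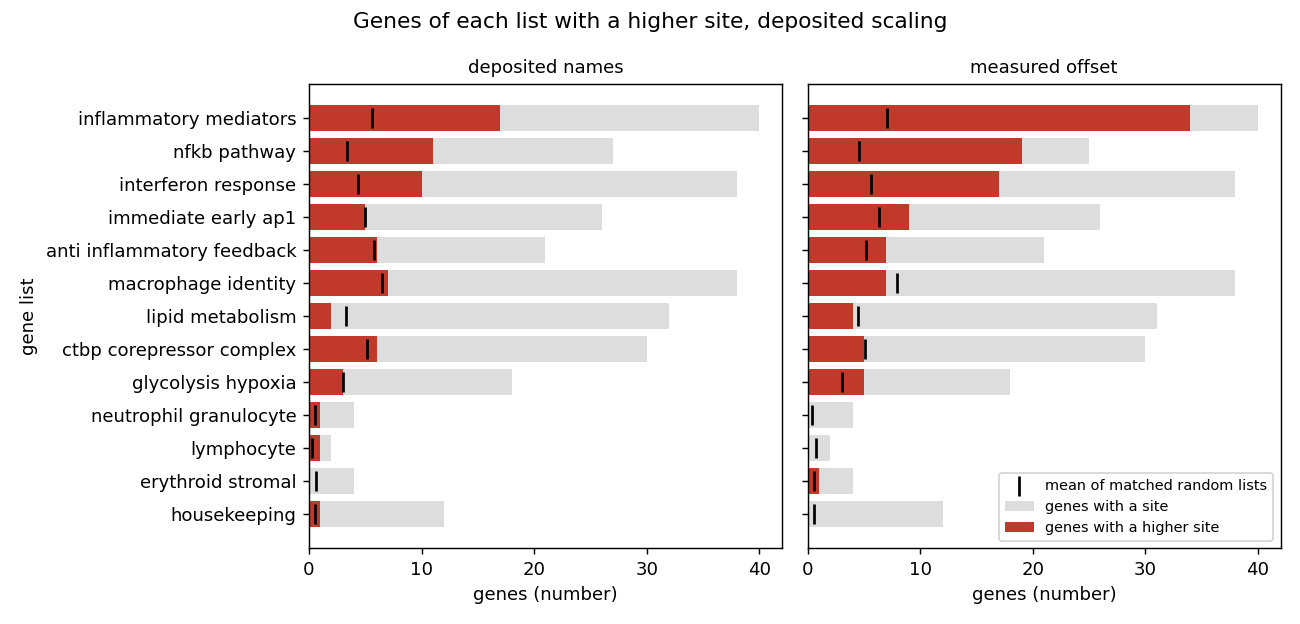
Genes per list (horizontal axis, number): grey, genes with a site; red, genes with a higher site; black marks, mean of matched random lists, under the names in the table (left) and the measured offset (right). Inflammatory mediators had 17 of 40 genes with a higher site under the table's names and 34 of 40 at the offset.

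The other 10 lists did not pass. At the offset, with table names in brackets, genes with a higher site were 9 of 26 (5 of 26) for immediate early and AP-1 genes, 7 of 21 (6 of 21) for anti-inflammatory feedback, 7 of 38 (7 of 38) for macrophage identity, and 4 of 31 (2 of 32) for lipid metabolism. They were 5 of 30 (6 of 30) for the CTBP co-repressor complex and 5 of 18 (3 of 18) for glycolysis. Single genes in them had higher sites under both namings. Those of Batf (log2 fold 2.97), Zeb1 (2.47) and Nr3c1 (2.33), which encodes the glucocorticoid receptor, kept the call without each library. They lay 20.0, 81.6 and 141 kb from the placed starts. Those of Ier5 (2.31) and Zeb2 (2.24, 1114 kb from the placed start) lost it without LPS replicate 3 (2.06 and 1.88), and that of Zeb2 also without vehicle replicate 1 (1.70). Those of Tfec (2.07) and Slc7a11 (2.10) lost it without vehicle replicate 1 or 2 and without LPS replicate 2 or 3. There the log2 folds were 1.72 to 2.15 and 1.78 to 2.20. The sites of Ier5, Tfec and Slc7a11 lay 22.1, 79.6 and 7.52 kb from the placed starts. A site 0.901 kb from the placed start of Socs3 (named Birc5), a feedback inhibitor of cytokine signalling, rose from 105 ± 55.1 to 444 ± 109 (SD, n = 3 each), a log2 fold of 2.15, and lost its call without LPS replicate 2 (2.14) or 3 (1.98). Markers of other cells were thinly covered. Neutrophil genes had a higher site in 0 of 4 (1 of 4), lymphocyte genes in 0 of 2 (1 of 2), erythroid or stromal genes in 1 of 4 (0 of 4), and housekeeping genes in 0 of 12 (1 of 12). By limma 0 genes of any of the 13 lists had a lower site, and at an unadjusted p under 0.05 between 0 and 8 genes per list did under the table's names and between 0 and 10 at the offset. On median-centred values genes with a lower site were many, such as 20 of 38 under the table's names and 27 of 38 at the offset for macrophage identity, 20 and 19 of 30 for the CTBP co-repressor complex, and 18 and 15 of 26 for immediate early and AP-1 genes. None of these 3 lists passed the test against matched lists there (permutation adjusted p from 0.583 to 1), while inflammatory mediators had fewer genes with a lower site than matched lists, 9 and 8 of 40 (permutation adjusted p = 0.026 and 0.00173). At the offset so did NF-kB (8 of 25, permutation adjusted p = 0.00728), interferon response (10 of 38, permutation adjusted p = 0.00953) and anti-inflammatory feedback genes (10 of 21, permutation adjusted p = 0.0163), none of which passed under the table's names. In camera with an estimated correlation, the median-centred lists of NF-kB and interferon response did not pass at the offset (adjusted p = 0.0767 and 0.189), and those of inflammatory mediators and anti-inflammatory feedback did (both 0.0476). Under the table's names the inflammatory mediator list did not pass there (camera adjusted p = 0.0705).

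Among the genes fixed in advance, Ctbp2, the macrophage regulator gene Spi1 and Actb had 0 sites called by limma in either naming. At an unadjusted p under 0.05, 2 of 6 Ctbp2 sites were lower under the table's names and 0 of 10 at the offset, 1 Spi1 site was higher in each naming and 0 Actb sites differed. On median-centred values limma called 2 of 6 Ctbp2 sites lower under the table's names and 3 of 10 at the offset, 1 of 5 and 4 of 11 Spi1 sites higher, and 2 of 7 and 1 of 6 Actb sites higher. The Ctbp2 site with the smallest adjusted p had a log2 fold of -1.15 under the table's names (nearest to Dhx32 at the offset, limma adjusted p = 0.267, and 1.05e-06 median-centred) and another of -0.70 at the offset (named Fam53b, limma adjusted p = 0.75, and 0.000218 median-centred). Ctbp1 had 2 of 15 sites higher under the table's names and 0 of 4 at the offset (0 at an unadjusted p under 0.05). Ccl2 had 1 of 26 higher under the table's names and 0 of 13 at the offset (1 at an unadjusted p under 0.05). Csf1r, which encodes the receptor for the macrophage growth factor M-CSF, had 0 of 1 higher under the table's names and 1 of 14 at the offset (log2 fold 1.57, named Slc26a2, limma adjusted p = 0.0388), a call lost without each library but vehicle replicate 3, with log2 folds of 1.36 to 1.68. On median-centred values Csf1r had 2 of 14 sites higher and 4 lower at the offset and 0 of 1 called under the table's names. Ctbp1 then had 5 of 15 higher and 4 lower under the table's names and 0 of 4 called at the offset, and Ccl2 10 of 26 higher and 1 lower, and 3 of 13 higher and 1 lower. Ifnb1 had no site in the table.

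By the table's own annotation, 0.849% of higher and 1.23% of uncalled sites overlapped a gene start, and these shares did not differ beyond sampling error (odds ratio 0.688, Fisher's exact test, two-sided, p = 0.284). On median-centred values the odds ratio was 0.786 (Fisher's exact test, two-sided, p = 0.0239). Site and gene positions are on different coordinates in most of the genome, so tests on the table's annotation say little about gene starts. At the measured offset, 42 of 1178 higher sites (3.57%) were centred within 1 kb of a placed gene start, against 6570 of 61017 uncalled sites (10.8%), an odds ratio of 0.306 (Fisher's exact test, two-sided, p = 2.46e-19). None of the 30 lower sites did in either naming (Fisher's exact test, two-sided, p = 1 and 0.0695). On median-centred values lower sites did so less often than uncalled sites, with an odds ratio of 0.557 by the table's annotation (Fisher's exact test, two-sided, p = 2.73e-06) and, at the offset, 292 of 8354 against 13.0% (odds ratio 0.242, Fisher's exact test, two-sided, p = 2.35e-175). Above the median concentration, 0 of 26 lower sites did at the offset, against 20.2% of uncalled sites (Fisher's exact test, two-sided, p = 0.00538).

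**Figure D4:**
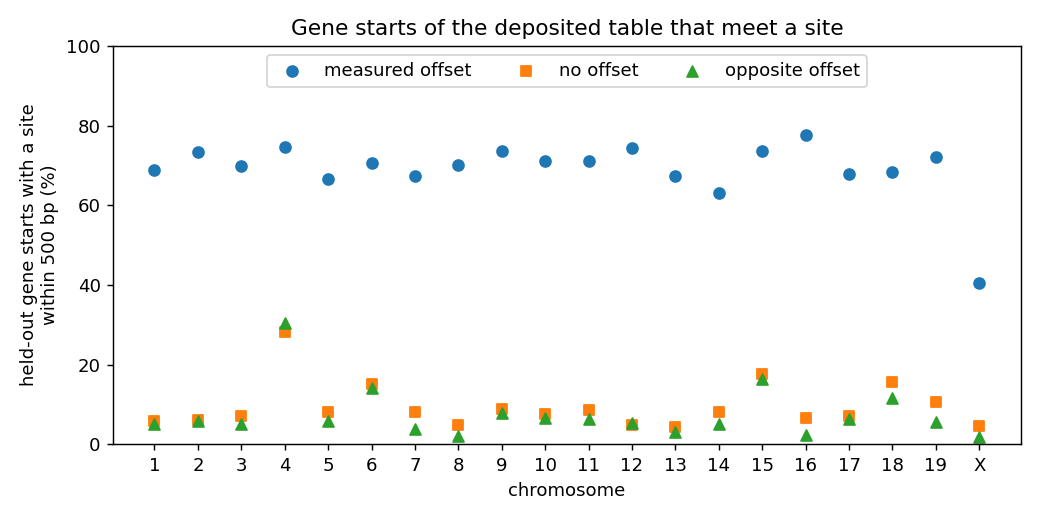
Share of held-out gene starts with a site within 500 bp (vertical axis, percent) on each chromosome, at the measured offset, with no offset and with the offset reversed. Over all chromosomes the shares were 70.1%, 9.61% and 7.96%.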

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

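Settings named here as added (median-centring with a block or a left-out library, the measured offset, centred list and promoter tests, the authors' calls, and lists without a library) were chosen after seeing the data. The counts of sites with higher CTBP2 signal in LPS and of sites with lower CTBP2 signal in LPS, 1178 and 30, were 641 and 5 at FDR 0.01, 9990 and 8354 median-centred, 9239 and 9637 quantile normalised, and 2497 and 230 both by Benjamini-Hochberg on the deposited p-values and in the authors' calls. Above the median concentration 695 were higher and 24 lower. Without a single library they ranged from 148 to 10062 and from 0 to 227. With median-centring they were 8777 and 6369, 8882 and 6169, and 10080 and 7875 without vehicle replicates 1, 2 and 3, and 8388 and 7671, 7618 and 5974, and 8282 and 6280 without LPS replicates 1, 2 and 3. Pseudocounts, a minimum fold, merging, autosomes and the low-value filter left both within 1.5 times. Centring kept 1174 of the higher and 30 of the lower sites. Centring subtracts 1 value per library, so it moves all log2 folds alike and takes out the spread in library level. At the Cxcl2 site the log2 fold went from 5.01 to 4.95 and its SE from 0.449 to 0.166. For the Tnfaip3 site the SE went from 0.454 to 0.2. The larger counts after centring go with the loss of that spread. What set the library levels was not tested.

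Whether the replicate numbers pair the libraries stays open. Deviations of same-numbered libraries correlated at 0.109, 0.0382 and 0.208, and those of differently numbered ones at -0.201 to 0.147. The value of 0.147 was that of vehicle replicate 2 with LPS replicate 1. With the replicate block the counts of sites with higher CTBP2 signal in LPS and of sites with lower CTBP2 signal in LPS were 6557 and 2179, and with centring and the block 11628 and 10351.

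Of 26 list tests, 2 passed. The number was 0 within 10 kb and within 1 kb of the named start, 1 with centring (fewer inflammatory genes with a lower site, 9 of 40) and 3 at FDR 0.01 and with lists matched on sites per gene alone, and 3 at the offset at any distance, within 10 kb and within 1 kb. At the offset with centring it was 8, and 7 within 10 kb. Without a library it ranged from 0 to 3. The promoter odds ratio for higher sites, 0.688 and not past the threshold, passed at the offset (0.306), at the offset with centring (0.427), with centring (0.786) and at the offset above the median concentration (0.205). The median log2 fold stayed within 1 SD of the library medians (0.461) in every setting, from -0.16 to 0.41. Of 116 named sites none changed direction with a call. Of their 82 calls, 42, 46 and 0 were lost without vehicle replicates 1, 2 and 3 and 15, 50 and 53 without LPS replicates 1, 2 and 3, and centring added 26. DESeq2, motif and GC alternatives were not run. On the deposited scaling the simulation recovered none of the 2-fold changes, so changes of that size were not detectable there. At the same simulated depth it recovered 75% of them on median-centred values.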

Other observations

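All tests of explanations in this part, and the genes named in it, were chosen after the results were seen. On the median-centred values, some genes with many sites had a large part of them called. At the offset, Itgb8, which encodes an integrin subunit, had 44 of 63 sites higher, Cd44 27 of 52 and Inhba, which encodes an activin subunit, 24 of 30, and among genes of the fixed lists Tnfaip3 had 35 of 45 and Nr3c1 26 of 53. Fat3 had 14 of 15 sites lower, Hmga2 14 of 33, and Cebpa, a myeloid transcription factor gene of the macrophage identity list, 13 of 23. These genes were picked by their counts, which were not tested against those of other genes. Anti-inflammatory feedback genes had a higher site in 20 of 21 at the offset with that scaling (matched mean 15.7, permutation adjusted p = 0.0357), and in 17 of 21 under the table's names (matched mean 15.2, permutation adjusted p = 0.954).

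Typical sites in vehicle replicate 3 were 2.03-fold above the other vehicle libraries (median log2 1.02). A single wrong scale factor would shift all sites alike. As the only cause it is argued against by the 20 sites of highest concentration, whose median shift was -0.12. Yet the rise of typical sites came with the factor. If 1 step is 1 read, vehicle replicates 1, 2 and 3 had a median of 41, 55 and 39 reads per site. There 1 read was worth 0.866, 0.678 and 1.87. A wrong factor along with another difference stays open. LPS replicate 3 against LPS replicate 1 showed a like split (median log2 0.687 over all sites, -0.699 at the 20). Stronger enrichment in vehicle replicate 3 may explain part of its rise, since sites at placed gene starts shifted more (1.26) than others (0.99). The 20 sites of highest concentration did not rise, so this stays open too. A difference between cultures was not tested and stays open.

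The 6 libraries can be split in 10 ways, too few for a share under 0.05. Of these, 2 gave as many higher sites as the real split (real 1178, highest other 22269). That other split, of vehicle 1, vehicle 2 and LPS 1 from the rest, sets the libraries of lowest median value against the others. Their medians were 35.5, 37.3 and 37.1, against 73.0, 48.8 and 61.0 in vehicle 3, LPS 2 and LPS 3. After centring limma called 0 sites for it, so its calls follow the library level. For lower sites 1 of 10 gave as many (real 30, highest other 9), and after centring 1 of 10 gave as many in either direction (real 18344, highest other 0 by limma).

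Few sites lay near the gene starts the table gives, 2.07% within 1 kb. Different coordinates for sites and genes account for part of this, since at the measured offset 70.1% of held-out gene starts met a site. Without the offset 9.61% did. Different builds may lie behind these coordinates. That CTBP2 sites lie away from gene starts stays open as a further part, since 10.6% of all sites lay within 1 kb of a placed start. In stretches with a shift under 1 kb, 12.1% of 2313 sites lay within 1 kb of the named start, which decides nothing because the shifts were picked by sites at gene starts. The gene columns follow GRCm38, since 83.5% of 8054 matched genes had a start or end within 100 bp of it, and the build of the sites stays open.

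Of the 10 largest gains, 6 lay within 10 kb downstream of a placed gene start, all of inflammatory mediator genes, and 4 within 1 kb of a gene end, which raised the question whether signal follows transcription. Over all higher sites 1 to 10 kb from a start, 46.0% lay downstream, against 55.5% of uncalled sites (Fisher's exact test, adjusted p = 0.049 over 7 such tests), and after centring 53.6% against 56.3% (adjusted p = 0.0973). For inflammatory mediator genes alone, a test added after that one and holding the 6 sites that prompted it, 72% of 25 higher sites lay downstream, against 44.2% of 77 uncalled sites (adjusted p = 0.049), and after centring 57.4% against 38.2% (adjusted p = 0.13). Among sites over 1 kb from a start, 2.20% of higher sites lay within 1 kb of a gene end, against 1.65% of uncalled sites (Fisher's exact test, adjusted p = 0.184). After centring the shares were 1.58% and 1.74% (Fisher's exact test, adjusted p = 0.286). On the deposited values 22.4% of these higher sites lay inside the nearest gene, against 29.7% (Fisher's exact test, adjusted p = 3.21e-07, not tested after centring). Signal that follows transcription and binding at those genes may both account for the gains and cannot be told apart, since both downstream tests passed under 1 scaling alone and in opposite directions, the sites of a gene are not independent, and no input or CTBP2-deficient control was analysed here.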
